A study of Homo sapiens with 12 samples.

How the data were processed

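RNA was measured by paired-end sequencing of polyA RNA in 12 libraries of teloHAEC, a telomerase-immortalized human aortic endothelial cell line. Per the labels, 3 independent clonal isolates in which the enhancer named ENH-5 had been removed (KO3, KO4 and KO5) and 3 WT control isolates (WT4, WT5 and WT6) were each kept for 14 days either in normoxia or in 1% oxygen. Libraries were pooled and sequenced together, so the labels give no sequencing batch. The oxygen level of the normoxic cultures is not given in the sources used here.

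The deposited tables list 208900 transcripts per library. Per the submitters' processing notes, STAR, RSEM, limma, edgeR and the genome build hg19 were used, with no versions given. The strand setting is not given in the sources used here. Per the file headers, each transcript has an expected count (a read count estimated by RSEM that need not be whole), a TPM value, an isoform percent within its gene, and a length and effective length. The deposited expected counts were the only values entered into tests. The isoform percent column deposited by the authors was used only to describe the EPAS1 transcripts, of which 1 held 90.29% to 100% per library. The deposited effective lengths, averaged per gene with the deposited TPM values as weights, served only for an alternative offset.

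Expected counts were summed over the transcripts of each gene identifier and rounded to whole numbers, which gave 60802 genes. Symbols, gene types, chromosome names, gene order, GC content and transcript length were taken from GENCODE release 29, which is on GRCh38. Of the identifiers, 93.4% matched, and the unmatched ones held at most 0.0729% of the counts of any library. Because the reference and the files are on different builds, no coordinates are printed.

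Library totals ranged from 29405360 to 31731535 expected counts, and 13311 to 13680 genes per library had at least 10 counts. The 10 most abundant genes took 7.139% to 9.188% of the counts. Counting intervals and floors are at 95% and use a floor of 3 counts per library. They cover counting error only. Replicate libraries were compared pairwise before averaging. Over the 12 within-group pairs, chi-square per degree of freedom was 27.0 to 258.8 and the correlation across genes of log2 values was 0.903 to 0.978, so no pair was treated as one library deposited more than once.

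Tests used edgeR 4.0.16 in R 4.3.3 with TMM normalization, the filterByExpr filter by group, robust dispersion estimates and the robust quasi-likelihood F test on 4 groups without further covariates. All 12 libraries entered each fit, with 8 residual degrees of freedom. The filter kept 14172 genes, and the common biological coefficient of variation was 0.319. P-values were adjusted by Benjamini-Hochberg over all genes tested in each comparison, with a threshold of 0.05. Standard errors were computed as the absolute log2 fold change divided by the square root of F. Group levels are CPM (counts scaled by TMM library size), given as mean ± SD of 3 clones. There were 5 comparisons: hypoxia against normoxia in WT, hypoxia against normoxia in KO, KO against WT in normoxia, KO against WT in hypoxia, and the difference between the responses (interaction). The replicates are separate clones, so p-values of KO against WT measure the spread between clones. In the hypoxia comparisons and the interaction each clone enters in both oxygen conditions, and the main fit treats its libraries as independent.

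Before the data were examined, 26 gene lists were fixed, and the 22 with at least 5 measured members were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of each comparison. The lists of smooth muscle and pericyte markers (4 measured), blood cell markers (2 measured), epithelial markers (4 measured) and mitochondrially encoded genes (0 measured) were too short to test. PECAM1 was not analysed here. The named genes followed a rule fixed at the same time: EPAS1, the 10 largest rises and 10 largest falls past the threshold with a mean of at least 1 CPM over all libraries and no overlap between the groups compared, leaving out clone-named, LOC, LINC, MIR, SNOR and antisense symbols, and from each list the 4 members with the smallest adjusted p plus any other member past the threshold. Values of a named gene in other comparisons could also be given. Genes high or low in KO5 by more than 10-fold against every WT clone, at 10 CPM or more on the higher side, served to compare clones. Chromosome medians of log2(CPM + 1) were taken over 10198 genes above 5 CPM, against the median of the 6 libraries of the same oxygen condition. Genes of the KO5 expression program and the interferon gene MX1 were chosen after their values were seen.

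Clone names recur in both oxygen conditions, so within a genotype the same number marks the same clone. Deviations from the group mean of the normoxic and hypoxic library of a clone correlated across genes at 0.56 in KO3, 0.06 in KO4, 0.55 in KO5, 0.40 in WT4, 0.42 in WT5 and 0.62 in WT6. Between different clones the correlations were -0.55 to 0.2 in KO and -0.44 to 0.16 in WT. Normoxic KO4 thus correlated no more with its own hypoxic library than with that of KO5 (0.2). On the basis of the names, clone was used as a block in an alternative fit of the hypoxia responses and the interaction. The numbers 4 and 5 name different clones in the 2 genotypes and pair nothing between them.

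The procedure was tested on simulated counts with 200 changed genes per comparison. For hypoxia against normoxia in WT, on 13970 genes, 36.4% of 2-fold and 74.7% of 4-fold changes were recovered with 6 false calls. For KO against WT in normoxia, on 13945 genes, the shares were 40.4% and 72.4% with 3 false calls. For the interaction, on 13940 genes, they were 6.3% and 45% with 1 false call. A simulated list shifted 1.5-fold was recovered in the same 3 comparisons (adjusted p = 4.31e-12, 2.98e-14 and 6.71e-06), and in the interaction 1 unshifted list also passed. The simulated genes were drawn independently, with no correlation between genes and no clone effects. The recovery of the list and the numbers of false calls therefore do not carry over to correlated genes or clones.

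Alternatives fixed at the same time were RLE size factors, DESeq2 1.42.0, limma-voom without and with a correlation within clone, no low-count filter (23846 genes), CPM above 1 in at least 3 libraries (12639 genes), an effective length offset, only the groups compared, the clone block, estimated inter-gene correlation or fry for lists, and leaving out each library in turn. Leaving out both libraries of KO3, KO4, KO5 or WT6, and the clone block with an estimated correlation for lists, were added after the data had been seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for summing counts, clone comparisons and plots. Transcript-level tests, splicing and the sequence of the enhancer were not analysed here.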

Results

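PolyA RNA was measured in 12 libraries of teloHAEC, human aortic endothelial cells immortalized with telomerase. The libraries formed 4 groups of 3: WT control clones and clones without the enhancer ENH-5 (KO), each after 14 days in normoxia or in 1% oxygen. The normoxic libraries held 30366473 (WT4), 30852497 (WT5), 29850609 (WT6), 30307466 (KO3), 31731535 (KO4) and 31330436 (KO5) expected counts. The hypoxic libraries held 30539445 (WT4), 29715583 (WT5), 29405360 (WT6), 30299270 (KO3), 30570401 (KO4) and 30634258 (KO5). Of 60802 gene identifiers, 14172 had enough counts to be tested. Per the labels the replicates are independent clonal isolates, although KO4 shared part of an expression program with KO5, as described below. P-values of KO against WT rest on the spread between clones, estimated from both libraries of each clone as if these were independent. The hypoxia comparisons and the interaction use both libraries of each clone, which the main fit treats as independent. Counting intervals and floors cover counting error only. The deposited values are on genome build hg19.

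EPAS1 (ENSG00000116016, chromosome 2), which encodes the hypoxia-inducible factor subunit HIF-2-alpha and is the gene the enhancer is assigned to, was measured first in every library. In normoxia its level was 950.4 CPM in WT4, 1122.8 in WT5, 712.9 in WT6, 1054.6 in KO3, 829.8 in KO4 and 718.8 in KO5. In hypoxia it was 369.8 CPM in WT4, 379.2 in WT5, 249 in WT6, 397.3 in KO3, 474.5 in KO4 and 387.3 in KO5. Between 7565 and 34831 counts lay behind each value. EPAS1 fell under hypoxia in WT, from 928.7 ± 205.8 to 332.6 ± 72.6 CPM, a ratio of 0.36 (95% interval 0.25 to 0.50, adjusted p = 0.00123). It fell in KO from 867.7 ± 171.1 to 419.7 ± 47.8 CPM, a ratio of 0.48 (0.34 to 0.68, adjusted p = 0.0104). Each hypoxic library lay below each normoxic library of its genotype, an arrangement chance gives in 10% of cases for 3 against 3. The KO to WT ratio was 0.93 in normoxia (0.67 to 1.31, adjusted p = 0.892) and 1.26 in hypoxia (0.90 to 1.76, adjusted p = 0.548). The responses differed by 0.43 on the log2 scale (SE 0.31, adjusted p = 0.987). KO and WT libraries overlapped in normoxia, while in hypoxia each KO library lay above each WT library, which chance also gives in 10% of cases. Removal of an enhancer takes away no part of the transcript, so its reads do not check the labels. The fall in KO was not past the threshold when both libraries of 1 clone were left out (adjusted p = 0.0691 without KO3, 0.0579 without KO4 and 0.0503 without KO5). The normoxic KO to WT difference changed sign without the normoxic KO5 library (log2 fold change 0.02) or the normoxic WT5 library (0.06).

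**Figure D1:**
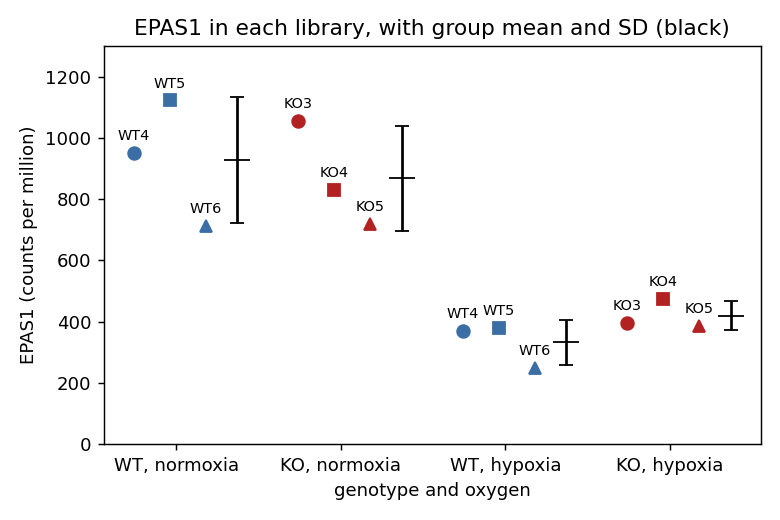
EPAS1 level in CPM in each of the 12 libraries, grouped by genotype and oxygen. The 6 hypoxic libraries sit between 249 and 474.5, and the 6 normoxic libraries between 712.9 and 1122.8.

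The first comparison asked what 14 days of hypoxia changed in WT endothelial cells. Known hypoxia targets were among the genes that rose. EGLN3 (ENSG00000129521), an oxygen-sensing prolyl hydroxylase, rose from 0.0966 ± 0.115 to 187 ± 12.1 CPM (log2 fold change 10.86, SE 0.49, adjusted p = 2e-06). ANKRD37 rose from 1.25 ± 0.164 to 42.9 ± 2.97 CPM (adjusted p = 1.75e-07), and the angiogenic peptide gene APLN from 179 ± 29.4 to 7170 ± 2250 CPM (adjusted p = 6.79e-05). The fibrillar collagen gene COL3A1 fell from 351 ± 303 to 0.715 ± 0.948 CPM (adjusted p = 0.0076), and LYVE1, a lymphatic and venous endothelial receptor, from 1220 ± 653 to 41.0 ± 28.8 CPM (adjusted p = 0.00123). In all, 1880 genes rose and 2156 fell, among them 513 and 1063 by more than 2-fold.

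Among core targets of hypoxia-inducible factor in WT, 19 of 26 members rose and none fell (20 rose and 1 fell adjusted over the list alone, list test adjusted p = 2.71e-25). The glucose transporter gene SLC2A1 rose from 36.2 ± 2.51 to 354 ± 59.6 CPM. The growth factor gene VEGFA rose by 3.30 on the log2 scale (SE 0.33), and PDK1, a kinase that inhibits pyruvate dehydrogenase, by 2.24 (SE 0.17). Of 19 glycolysis genes, 15 rose by either adjustment (adjusted p = 5.61e-18). TPI1 went from 359 ± 23.3 to 1180 ± 111 CPM, ALDOA from 655 ± 36.1 to 1830 ± 115 CPM and GAPDH from 2830 ± 73.1 to 6780 ± 541 CPM. Both lists also passed with an estimated correlation (adjusted p = 8.17e-05 and 0.00124). Nuclear respiratory chain genes rose too, 16 of 28 (19 adjusted over the list alone, adjusted p = 6.47e-08, and adjusted p = 0.256 with an estimated correlation). CYC1 rose by 0.88 (SE 0.10) and COX7A2 by 1.10 (SE 0.13).

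Most proliferation genes that passed in WT rose. Of 32 members, 17 rose and 2 fell (20 and 2 adjusted over the list alone), and the list passed toward higher (adjusted p = 9.96e-09, but adjusted p = 0.473 with an estimated correlation). The replication gene MCM7 went from 37.5 ± 1.18 to 102 ± 14.1 CPM, and PCNA rose by 1.19 (SE 0.12) and E2F1 by 2.45 (SE 0.42) on the log2 scale. The mitotic genes AURKB and BIRC5 also rose, by 1.58 (SE 0.30) and 1.22 (SE 0.35). The members MKI67 and CENPF fell by 1.66 (SE 0.48) and decreased by 1.84 (SE 0.55).

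Venous and lymphatic markers fell in WT, 7 of 9 (8 adjusted over the list alone, adjusted p = 8.74e-06, and adjusted p = 0.0914 with an estimated correlation). NR2F2, a venous identity regulator, fell from 403 ± 50.1 to 88.2 ± 15.9 CPM and STAB1 from 255 ± 63.3 to 55.7 ± 16.5 CPM. Matrix genes fell as a list, 12 of 30 against 4 that rose (14 and 4 adjusted over the list alone, adjusted p = 0.00831, and adjusted p = 0.473 with an estimated correlation). MMP2 fell by 2.46 (SE 0.35) and FBN1 fell by 1.81 (SE 0.32), while the collagen-modifying enzyme genes PLOD2 and P4HA1 rose by 1.14 (SE 0.22) and 1.19 (SE 0.16). The matrix list did not pass without both WT6 libraries (adjusted p = 0.0829). Of 16 arterial and Notch genes, 1 rose and 4 fell (2 and 5 adjusted over the list alone, adjusted p = 0.154), the ligand gene JAG1 going from 150 ± 19.4 to 45.5 ± 9.87 CPM.

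Endothelial identity genes moved both ways in WT, with 3 of 25 higher and 7 lower (3 and 8 adjusted over the list alone, adjusted p = 0.108). KDR, the main VEGF receptor gene, fell from 705 ± 54.3 to 214 ± 14.5 CPM and VWF from 3030 ± 953 to 577 ± 407 CPM, while EGFL7 rose from 98.9 ± 32.7 to 333 ± 73.4 CPM. HIF-2-linked genes split as well, 3 higher and 6 lower of 21 (5 and 6 adjusted over the list alone, adjusted p = 0.966), and their median (0.12) and mean (0.47) were above 0 while the test pointed down. The adenosine receptor gene ADORA2A rose from 2.78 ± 1.73 to 111 ± 65.9 CPM, and the nitric oxide synthase gene NOS3 fell by 1.58 (SE 0.45). Of 11 HIF pathway components, 2 rose and 4 fell (adjusted p = 0.312, with a median of -0.35, a mean of 0.45 and a test pointing up), among them HIF1A, which went from 411 ± 42.9 to 205 ± 14.0 CPM. Of 11 measured genes near EPAS1, RHOQ, LINC01119 and CALM2 rose and SRBD1 fell (adjusted p = 0.197).

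Other WT lists had no shared direction past the threshold. Of 23 vasoactive and haemostatic genes, 4 rose and 7 fell (4 and 9 adjusted over the list alone, adjusted p = 0.312), the angiotensin-converting enzyme gene ACE going from 38.5 ± 21.6 to 2.47 ± 1.39 CPM and the prostacyclin synthase gene PTGIS from 47.5 ± 42.5 to 281 ± 112 CPM. Of 20 tip cell and angiogenesis genes, 5 rose and 2 fell (6 and 3 adjusted over the list alone, adjusted p = 0.197). Mesenchymal transition genes rose in 3 and fell in 5 of 18 cases (4 and 7 adjusted over the list alone, adjusted p = 0.43), TAGLN going from 3.42 ± 0.434 to 97.0 ± 60.3 CPM and FN1 from 5790 ± 1930 to 687 ± 527 CPM. BMP and TGF-beta genes rose in 3 and fell in 3 of 20 cases by either adjustment (adjusted p = 0.197), LTBP1 going from 769 ± 56.1 to 160 ± 21.8 CPM. Unfolded protein and amino acid response genes rose in 5 and fell in 4 of 20 cases (adjusted p = 0.331), ASNS by 2.59 (SE 0.39). Among 21 p53 targets, 4 rose and 1 fell (adjusted p = 0.197), DDB2 by 1.33. Among 23 cholesterol genes, STARD4 and INSIG1 rose (1 adjusted over the list alone, adjusted p = 0.197), and among 18 oxidative stress and metal genes, SLC40A1 and TFRC fell (1 adjusted over the list alone, adjusted p = 0.921, with a median of 0.14, a mean of -0.11 and a test pointing down). B2M rose among 30 interferon genes (0 adjusted over the list alone, adjusted p = 0.417) and IL6 among 16 inflammatory genes (adjusted p = 0.921, median 0.09, mean -0.11). Fibroblast markers (1 rose and 1 fell of 5, adjusted p = 0.966) had a median of -1.34 and a mean of -2.35 while the test pointed up.

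Several of the largest WT changes involved genes near the detection floor in 1 condition. SRARP, at 0 counts in normoxia, was at least 286-fold higher in hypoxia against a floor of 3 counts per library. ENKUR was 568 times its normoxic level (counting interval 157 to 4700), the carbonic anhydrase gene CA2 467 times (83.4 to 18500) and the angiotensin receptor gene AGTR1 266 times (47.3 to 10500). DEPP1, GALNT18, FAM131C and N4BP3 rose by 6.38, 5.64, 5.59 and 5.33 on the log2 scale. C11orf87 was 403 times (72.0 to 16000) and CA8 286 times (78.7 to 2360) as high in normoxia as in hypoxia. ANGPTL1, NTN1, CHI3L2, RTN4RL1, NTS, ABCA9 and PCDH19 had log2 fold changes of -7.63, -7.10, -6.04, -5.96, -5.28, -5.25 and -5.24. Without the normoxic WT5 library 2541 genes passed in place of 4036, and with a correlation within clone in limma-voom 6184 did. Of the lists too short to test, only the smooth muscle and pericyte marker SMTN passed (log2 fold change -1.34), while no blood cell or epithelial marker did.

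In KO clones the same comparison asked what hypoxia changed without the enhancer. KO4 was closer to KO5 in normoxia than in hypoxia, with medians of 74.9% and 44.4% of the KO5 level above WT. These medians are over genes described below, picked separately in each condition. In KO4 this difference was not separated from the effect of oxygen, and it enters the KO response and the interaction. EGLN3 rose from 0.115 ± 0.0340 to 132 ± 22.6 CPM (log2 fold change 10.11, SE 0.48, adjusted p = 3.08e-06), ANKRD37 from 0.906 ± 0.189 to 40.8 ± 3.69 CPM (adjusted p = 1.05e-07) and APLN from 426 ± 201 to 7790 ± 1080 CPM (adjusted p = 0.000287). LYVE1 fell from 1740 ± 714 to 8.26 ± 3.29 CPM (adjusted p = 0.000569), COL3A1 from 119 ± 144 to 0.123 ± 0.118 CPM (adjusted p = 0.0134) and the acid phosphatase gene ACP5 from 268 ± 42.4 to 4.57 ± 3.70 CPM (adjusted p = 0.00214). In all, 1141 genes rose and 1445 fell, 344 and 635 of them by more than 2-fold.

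Core targets of hypoxia-inducible factor rose in KO as well, 18 of 26 with none falling (20 adjusted over the list alone, adjusted p = 2.23e-39). SLC2A1 went from 38.6 ± 10.6 to 602 ± 214 CPM and VEGFA from 2.97 ± 1.31 to 50.8 ± 10.6 CPM, and NDRG1 rose by 2.53 (SE 0.33) on the log2 scale. Of 19 glycolysis genes, 15 rose (16 adjusted over the list alone, adjusted p = 8.79e-24), ALDOA by 1.56 (SE 0.12), TPI1 by 1.64 (SE 0.13) and LDHA by 1.41 (SE 0.17). These lists passed with an estimated correlation too (adjusted p = 9.45e-06 and 0.000646). Respiratory chain genes rose in 14 of 28 cases (16 adjusted over the list alone, adjusted p = 9.46e-07, and adjusted p = 0.241 with an estimated correlation), COX7A2 by 0.84 (SE 0.13) and CYC1 by 0.62 (SE 0.10). Cholesterol genes passed toward higher (adjusted p = 0.0254, and adjusted p = 0.927 with an estimated correlation), STARD4, INSIG1 and IDI1 being the 3 of 23 that rose (2 adjusted over the list alone). This list did not pass without the normoxic KO3 library (adjusted p = 0.217), the hypoxic KO5 library (0.287) or both KO5 libraries (0.0607).

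Venous and lymphatic markers fell in KO, 5 of 9 (8 adjusted over the list alone, adjusted p = 2.49e-06, and adjusted p = 0.0566 with an estimated correlation), among them STAB1, from 206 ± 18.3 to 53.8 ± 24.9 CPM, and NR2F2, from 256 ± 123 to 82.8 ± 23.6 CPM. Arterial and Notch genes fell as a list, 5 of 16 against 1 that rose (7 and 1 adjusted over the list alone, adjusted p = 0.0148, and adjusted p = 0.188 with an estimated correlation). JAG1 went from 100 ± 19.0 to 38.3 ± 2.99 CPM and the Notch target gene HEY1 from 3.74 ± 2.80 to 0.225 ± 0.149 CPM. That call was lost without the normoxic KO4 library (adjusted p = 0.067), the hypoxic KO4 library (0.0541) or both (0.149). HIF pathway components passed toward higher (2 of 11 rose and 2 fell, 3 and 5 adjusted over the list alone, adjusted p = 0.0217, and adjusted p = 0.112 with an estimated correlation), with a median of -0.24 below 0 and a mean of 0.75 above it. EGLN1 rose by 2.45 (SE 0.24), while VHL fell by 1.03 and HIF1A decreased by 1.01. The list did not pass without the normoxic KO5 library (adjusted p = 0.0584), both KO4 libraries (0.0823) or both KO5 libraries (0.0546).

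Endothelial identity genes in KO showed 2 of 25 higher and 5 lower (2 and 6 adjusted over the list alone, adjusted p = 0.186), KDR going from 959 ± 301 to 174 ± 18.6 CPM and VWF from 3580 ± 971 to 1010 ± 228 CPM. Of 21 HIF-2-linked genes, 2 rose and 5 fell (3 and 6 adjusted over the list alone, adjusted p = 0.959, with a median of -0.18, a mean of 0.09 and a test pointing down). Proliferation genes were divided, MCM7, PCNA and MCM2 rising and CENPF, MKI67, FOXM1 and KIF20A falling (3 and 5 adjusted over the list alone, adjusted p = 0.959). Matrix genes rose in 3 and fell in 7 of 30 cases (adjusted p = 0.401), mesenchymal genes in 3 and 5 of 18 (5 and 6 adjusted over the list alone, adjusted p = 0.841), and BMP and TGF-beta genes in 4 and 5 of 20 (6 and 6 adjusted over the list alone, adjusted p = 0.959). SMAD7 and SMAD6, which restrain BMP and TGF-beta signalling, each rose by 1.66. Vasoactive genes rose in 2 and fell in 5 of 23 cases (6 and 8 adjusted over the list alone, adjusted p = 0.959), and tip cell genes in 4 and 2 of 20 (adjusted p = 0.418, with a median of -0.19, a mean of 0.18 and a test pointing up). Oxidative stress and metal genes had 2 higher and 2 lower members of 18 (adjusted p = 0.959, median -0.06, mean 0.01), p53 targets 2 higher of 21 (adjusted p = 0.406) and unfolded protein genes 2 higher and 1 lower of 20 (adjusted p = 0.618). CALM2 rose among the neighbours of EPAS1 (0 adjusted over the list alone, adjusted p = 0.201) and IL6 among inflammatory genes (adjusted p = 0.959, with a median of -0.15, a mean of -0.23 and a test pointing up). No interferon gene passed (adjusted p = 0.586), and 1 fibroblast marker rose and 1 fell of 5 (1 and 2 adjusted over the list alone, adjusted p = 0.959).

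Other large KO changes began or ended near the floor. SRARP was at least 126-fold and C5orf46 at least 44.8-fold higher in hypoxia, against 3 counts per library, and ENKUR was 369 times its normoxic level (counting interval 102 to 3050). SMIM43, CA2, FPR3, SYTL2 and FAM131C rose by 8.21, 7.54, 6.46, 6.40 and 5.99 on the log2 scale. ABCA9, ACSM3, CYP1A1, EGR1, PAPLN, BCRP3 and ABCA6 had log2 fold changes of -7.68, -6.88, -5.37, -5.36, -5.31, -5.21 and -4.93. With clone as a block 2102 genes were higher and 2582 lower (4684 in all), and with a correlation within clone 4923 passed. Single libraries moved the count of 2586 by more than 1.5 times: it was 1577 without hypoxic KO3, 1628 without hypoxic KO5, 1130 without normoxic KO4 and 1497 without normoxic KO5. It was 1656, 706 and 830 without both libraries of KO3, KO4 and KO5.

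Whether both genotypes changed the same genes was asked next, from responses that share no library. Across 14172 genes, which are not independent replicates, the log2 fold changes in KO and WT correlated at Pearson's r 0.727 and Spearman's rho 0.739. Both rose for 905 genes, where independent lists would share 151, and both fell for 1169, where 220 would be shared. A single gene passed in opposite directions. Of the 4036 genes past the threshold in WT, 97.9% had the same sign in KO, and 83.4% had a smaller change there, genes being picked here by their change in WT. The slope of the KO on the WT log2 fold changes over all genes was 0.699. Their SD was 1.004 in WT and 0.965 in KO. A correlation of 0.727 lowers the slope even where the spreads are equal, so the slope does not by itself measure a weaker response in KO. Between single clones of different genotype the correlation was 0.447 to 0.749.

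**Figure D2:**
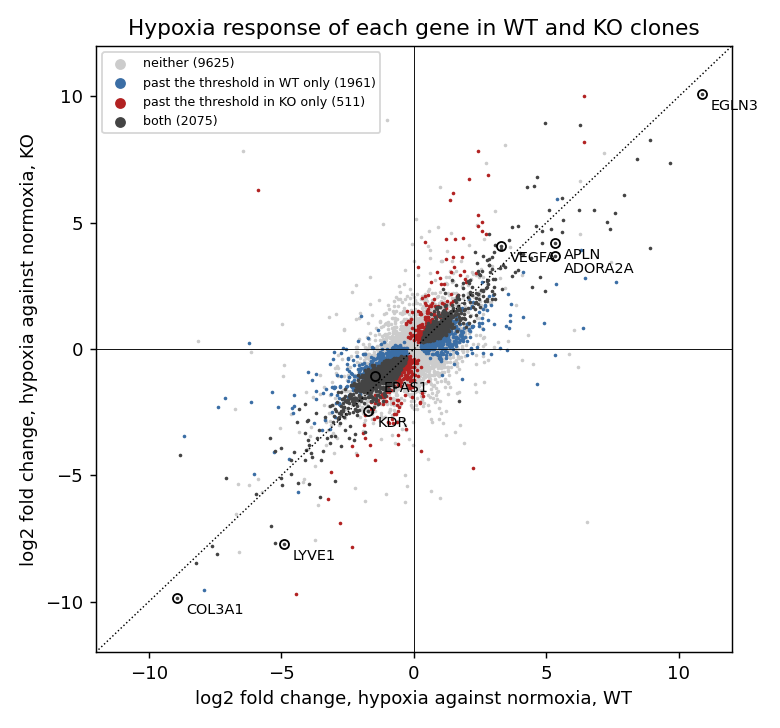
Log2 fold change under hypoxia in WT (horizontal) against KO (vertical), 1 point per gene, coloured by which response passed the threshold. Of the 2075 genes past the threshold in both, 905 rose in both and 1169 fell in both, while 1961 passed in WT only, 511 in KO only and 9625 in neither.

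**Figure D3:**
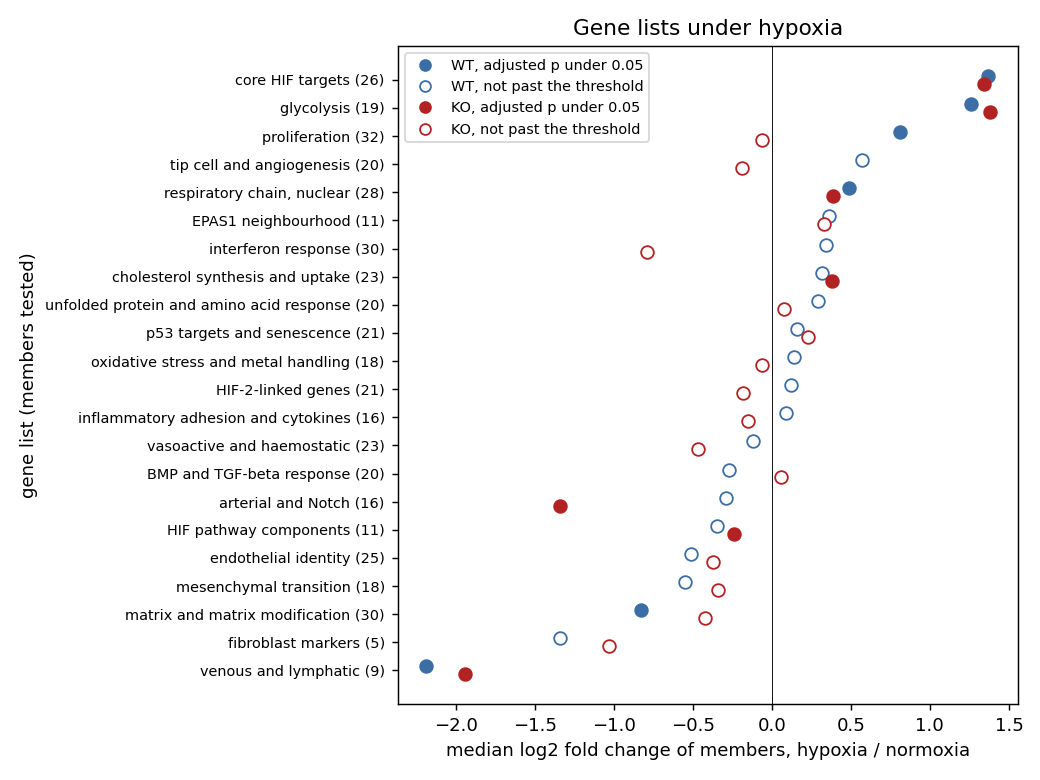
Median log2 fold change of the members of each of 22 gene lists under hypoxia in WT and KO, with filled points for lists whose test passed. Core HIF targets, glycolysis, the respiratory chain and venous markers are filled in both genotypes, and for HIF pathway components in KO the test pointed up while the median was -0.24.

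The comparison of KO with WT in normoxia asked what removal of the enhancer did without added hypoxia. TUBA4A (ENSG00000127824, chromosome 2), an alpha tubulin gene, was the only gene past the threshold, at 3.98 ± 0.747 CPM in WT and 12.6 ± 1.79 CPM in KO (log2 fold change 1.66, SE 0.19, adjusted p = 0.0462). It was between 11.2 and 14.6 CPM in the KO clones and between 3.46 and 4.84 CPM in the WT clones, an absence of overlap that chance gives in 10% of cases. At an unadjusted p under 0.05 there were 1399 genes, 9.9% of those tested. DESeq2 called 119 higher and 35 lower, limma-voom 0, edgeR without the low-count filter 3, and edgeR with a length offset or with only the groups compared 0. Without normoxic KO3 the count was 305 higher and 101 lower, without any other normoxic library it was 0, and without both KO3 libraries it was 553 higher and 216 lower.

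No list had a member past the threshold over all genes in this comparison, but 6 lists passed their test, and none did with an estimated correlation. Proliferation genes were higher in KO (median log2 fold change 0.59, adjusted p = 1.36e-11, and adjusted p = 0.358 with an estimated correlation), for example MCM6 at 50.9 ± 6.63 against 35.9 ± 3.85 CPM. The list score (mean log2 difference of its members from their means over all libraries) was -0.34 in KO3, 0.29 in KO4 and 0.42 in KO5, against -0.51 in WT4, -0.34 in WT5 and -0.41 in WT6. Cholesterol genes were higher (median 0.69, adjusted p = 1.07e-08, and adjusted p = 0.358 with an estimated correlation), with DHCR7 at 147 ± 78.4 against 51.4 ± 14.8 CPM and list scores of -0.27 in KO3, 0.39 in KO4 and 0.50 in KO5 against -0.77 to -0.34 in WT clones. Tip cell genes were higher (median 0.81, 4 members adjusted over the list alone, adjusted p = 0.000186, and adjusted p = 0.358 with an estimated correlation). Their member ANGPT2, a vessel-destabilizing ligand gene, was at 178 ± 158 CPM in KO and 1.05 ± 0.245 CPM in WT. The mean of CXCR4 in KO was 1470 times that in WT (counting interval 504 to 7140), from 59.0 CPM in KO4 and 80.6 CPM in KO5 with 0 CPM in KO3. Arterial and Notch genes were higher (4 higher and 1 lower adjusted over the list alone, adjusted p = 0.0197, and adjusted p = 0.358 with an estimated correlation), with EFNB2 at 30.9 ± 24.7 against 2.89 ± 1.21 CPM. ANGPT2 was likewise 1.05 CPM in KO3, 229 in KO4 and 305 in KO5. The scores of the tip cell list were -0.99, 0.94 and 1.06 and those of the arterial list -0.15, 1.34 and 1.27 in KO3, KO4 and KO5, with KO3 below the WT clones in both lists.

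Venous and lymphatic markers were lower in normoxic KO (median -0.51, adjusted p = 0.0292, and adjusted p = 0.358 with an estimated correlation), a call lost without normoxic KO3 (adjusted p = 0.293), KO5 (0.0993), WT4 (0.413), WT5 (0.101) or WT6 (0.146). Their list scores were 1.42 in KO3, 1.06 in KO4 and -0.19 in KO5, against 2.01 in WT4, 1.42 in WT5 and 1.44 in WT6. Interferon genes were lower (median -1.15, adjusted p = 0.0197, and adjusted p = 0.699 with an estimated correlation), and this direction turned with 1 clone. The median interferon gene stood at 296 CPM in normoxic WT6 and at 22.9 to 37.8 CPM in the other normoxic libraries, and without normoxic WT6 the list was higher in KO (adjusted p = 0.0295). It did not pass without normoxic KO3 (adjusted p = 0.293). The other 16 lists had adjusted p between 0.0548 and 0.998, with a median of -0.09 for core HIF targets, 0.25 for HIF-2-linked genes and -0.11 for the neighbours of EPAS1. The scores of HIF-2-linked genes were -0.52 in KO3, 0.62 in KO4 and 0.56 in KO5, against -0.58 to -0.47 in WT clones. Among these 16 lists were the fibroblast markers, of which 5 were measured. Their median was 1.58, 2 were higher adjusted over the list alone, and the adjusted p was 0.0548 (0.358 with an estimated correlation). With 1 library left out they passed without normoxic KO4 (0.0386), KO5 (0.000271), WT4 (0.0116), WT5 (0.0444) or WT6 (0.00688), but not without KO3 (0.293). Their scores were 1.49 in KO3, 1.57 in KO4 and -0.07 in KO5 against 0.73 to 1.10 in WT clones. The members FAP (12.4 ± 1.40 against 4.17 ± 1.35 CPM) and COL1A2 (50.2 ± 26.6 against 11.7 ± 7.15 CPM) did not overlap between KO and WT libraries and were not past the threshold over all genes. Genes with group means far apart but not past the threshold included LOX (355 ± 302 against 12.2 ± 4.27 CPM), TFPI2 (286 ± 254 against 2.41 ± 1.85) and the pericyte marker RGS5 (17.6 ± 22.1 against 442 ± 457).

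**Figure D4:**
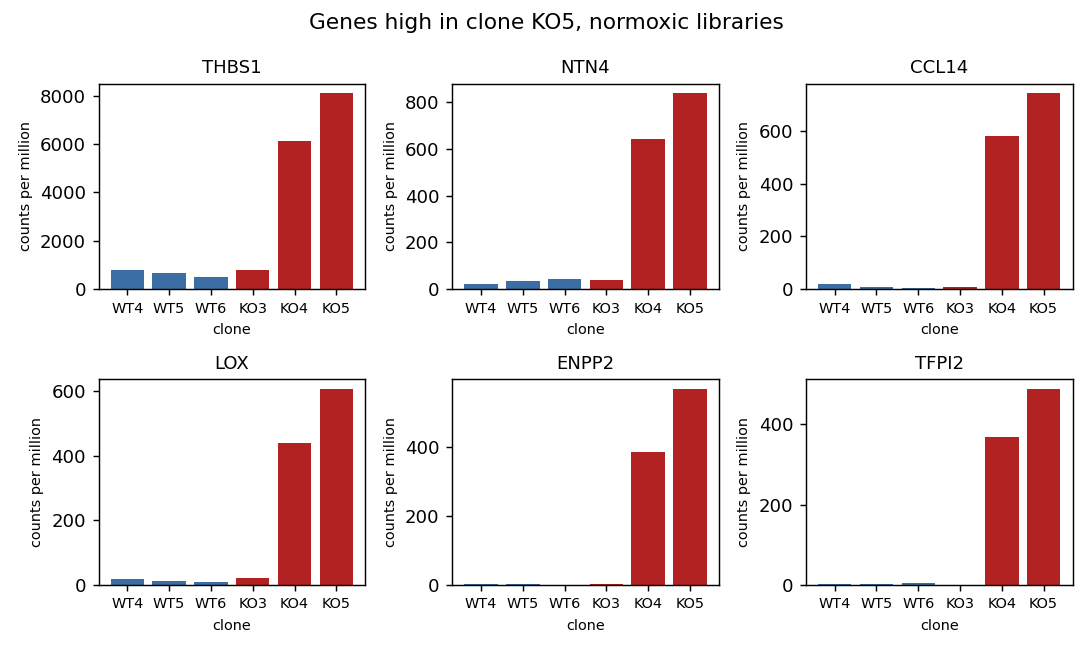
Level in CPM of 6 genes in the normoxic library of each clone, each bar 1 library. THBS1, NTN4, CCL14, LOX, ENPP2 and TFPI2 are high in KO5 and KO4 and lower in KO3, as for LOX at 607, 439 and 20.3.

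In hypoxia, the comparison of KO with WT asked what differed after 14 days at low oxygen. No gene passed the threshold in edgeR, with 1502 genes (10.6% of those tested) at an unadjusted p under 0.05. TUBA4A came closest, at 16.6 ± 3.18 CPM in KO and 5.39 ± 0.330 CPM in WT (log2 fold change 1.63, adjusted p = 0.0538). DESeq2 called 59 genes higher and 18 lower, limma-voom 0, edgeR without the low-count filter 1 and with a length offset 1. Without hypoxic KO3 the count was 7, and without both KO3 libraries 228.

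In this comparison 7 lists passed with the preset correlation, and each had an adjusted p = 0.437 with an estimated correlation. Cholesterol genes were higher in hypoxic KO (median 0.92, 13 of 23 adjusted over the list alone, adjusted p = 2.91e-12), with IDI1 at 135 ± 50.4 against 70.6 ± 12.6 CPM and MSMO1 at 350 ± 186 against 130 ± 40.0 CPM. The list score was 0.06 in KO3, 0.62 in KO4 and 1.06 in KO5, against -0.17 in WT4, -0.07 in WT5 and -0.51 in WT6. BMP and TGF-beta genes were higher (median 0.32, 1 adjusted over the list alone, adjusted p = 0.00772), with BMP6 at 499 ± 209 against 253 ± 22.6 CPM and scores of -0.17 in KO3, 0.35 in KO4 and 0.58 in KO5 against -0.58 to 0.04 in WT clones. Proliferation genes were lower (median -0.45, adjusted p = 5.88e-08), with PCNA at 143 ± 18.2 against 186 ± 8.35 CPM and scores of 0.17 in KO3, 0.00 in KO4 and -0.38 in KO5 against 0.78 in WT4, 0.07 in WT5 and 0.23 in WT6. Interferon genes were lower (median -2.53, adjusted p = 4.22e-08), with IFIT1 at 6.82 ± 2.46 against 314 ± 520 CPM, and the median interferon gene stood at 376 CPM in hypoxic WT6 against 10.8 to 21.8 CPM in the other hypoxic libraries. Without hypoxic WT6 the interferon list did not pass (adjusted p = 0.245). Tip cell genes were higher (median 0.34, adjusted p = 0.0127), not past the threshold without hypoxic KO5 (0.0601) or WT4 (0.0758), with scores of -0.17 in KO3 and at least 0.92 in KO4 and KO5 against -0.53 to 0.19 in WT clones. P53 targets were lower (median -0.26, adjusted p = 0.0161), not past it without hypoxic KO5 (0.134), with scores of 0.15 in KO3, 0.05 in KO4 and -0.21 in KO5 against 0.18 to 0.30 in WT clones. HIF-2-linked genes were higher (median 0.25, 1 adjusted over the list alone, adjusted p = 0.0487), with CITED2 at 44.0 ± 12.1 against 23.5 ± 5.70 CPM, a call lost without hypoxic KO4 (0.104), KO5 (0.0675), WT4 (0.0758) or WT6 (0.177). Their scores were -0.05 in KO3, 0.66 in KO4 and 0.68 in KO5 against -0.49 to 0.13 in WT clones, so that KO3 lay within the WT range for the BMP, proliferation, tip cell and HIF-2-linked lists. The other 15 lists had adjusted p between 0.0535 and 0.836.

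The interaction asked whether hypoxia acted differently in KO and WT. No gene passed the threshold in edgeR (smallest adjusted p 0.987), DESeq2 called 1 higher and 1 lower, and limma-voom called 0. In edgeR 698 genes (4.9%) had an unadjusted p under 0.05, about the share this cutoff gives where no gene differs. Simulated 2-fold differences were recovered in 6.3% of genes in this comparison and 4-fold differences in 45% of genes. TGFB1, which fell by 1.57 on the log2 scale in WT and decreased by 0.62 in KO, had a difference of 0.96 (SE 0.20, adjusted p = 0.987).

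Of the lists, 4 passed the test of this difference, and none did with an estimated correlation. Proliferation genes differed downward in KO (median difference -1.09, 20 of 32 lower adjusted over the list alone, adjusted p = 2.68e-30, and adjusted p = 0.288 with an estimated correlation), with AURKB at -1.69 (SE 0.42) and BIRC5 at -1.57 (SE 0.49). The mean response of the list was 0.52 in KO3, -0.27 in KO4, -0.76 in KO5, 1.25 in WT4, 0.40 in WT5 and 0.64 in WT6, so KO3 lay within the range of the WT clones. Matrix genes differed upward (median 0.32, adjusted p = 0.0019, and adjusted p = 0.428 with an estimated correlation), with MMP2 at 1.60 (SE 0.47) and COL8A1 at 2.16 (SE 0.73). BMP and TGF-beta genes did too (median 0.49, 1 adjusted over the list alone, adjusted p = 0.00512, and adjusted p = 0.288 with an estimated correlation). Neither list passed without normoxic WT6 (adjusted p = 0.0792 for matrix and 0.0792 for BMP genes) or hypoxic KO5 (0.0697 and 0.0702), nor the BMP list without normoxic KO3 (0.0754). The mean responses in KO3, KO4 and KO5 were -0.55, -0.32 and 0.11 for matrix genes, against -0.53, -0.34 and -1.12 in WT4, WT5 and WT6, and -0.08, 0.14 and 0.35 for BMP genes, against -0.17, 0.05 and -0.59, so KO3 lay within the WT range in both. Interferon genes differed downward (median -1.01, adjusted p = 0.00512, and adjusted p = 0.873 with an estimated correlation). That call was lost without normoxic WT4 (0.203), normoxic WT5 (0.4) or hypoxic KO5 (0.0702), and pointed the other way without hypoxic WT6 (0.0886). The latter fit keeps normoxic WT6, where interferon genes were high, without its pair. Mean responses of the list were 0.19 in KO3, -0.7 in KO4 and -1.55 in KO5. They were 0.08, 0.11 and 0.31 in WT4, WT5 and WT6, with KO3 inside the WT range. The other 18 lists had adjusted p between 0.142 and 0.982, core HIF targets and glycolysis among them. With clone as a block, core HIF targets passed as well.

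Some libraries stood apart from the rest of their group in genes chosen after their values were seen. In normoxia, 41 genes were high and 49 were low in KO5 by more than 10-fold against every WT clone. THBS1, a matrix glycoprotein gene, was 8090 CPM in KO5 and 6110 in KO4, against 766 in KO3 and 490 to 794 in the WT clones. On the 41 genes KO4 had a median of 74.9% of the KO5 level above WT. On the 49 low genes, such as ELN at 0.122 CPM in KO5, 135 in KO4 and 470 in KO3, it kept 24.0% of the WT level. In hypoxia the shares were 44.4% on 31 genes and 52.7% on 30 genes. KO3 had 0.0% in normoxia and 1.4% in hypoxia on the high genes. Genes of chromosome 11 were higher in KO5, with a median log2 difference from the median of the 6 libraries of 0.37 in normoxia and 0.44 in hypoxia over 614 genes. Chromosome 20 differed among most clones, with normoxic and hypoxic medians over 292 genes of 0.24 and 0.35 in KO5, 0.20 and 0.18 in WT5, 0.17 and 0.04 in KO4, -0.23 and -0.17 in KO3, -0.22 and -0.17 in WT4 and -0.12 and -0.04 in WT6. In WT6, genes of chromosome 1 had medians of -0.25 in normoxia and -0.24 in hypoxia over 1007 genes, and chromosomes 6, 15 and 22 had normoxic medians of -0.25, -0.24 and -0.24. MX1, an interferon-induced antiviral gene, was 1160 CPM in normoxic and 1270 CPM in hypoxic WT6 and at most 104 CPM in any other library. Counts of GAPDH, TPI1, ALDOA, LDHA, CALM2 and other genes with near-identical copies or pseudogenes, and of tubulin, interferon and metallothionein families, depend on how RSEM shared reads among copies, and since the strand setting is not given in the sources used here, overlapping antisense genes are uncertain too.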

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

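The estimated correlation was chosen in advance as an alternative, but its use to weigh the proliferation difference, and the other tests in this part, were chosen only after the results were seen. In 4 gene lists the response to oxygen differed between KO and WT clones when the preset correlation was used. They were proliferation (adjusted p = 2.68e-30, and 0.288 with an estimated correlation), matrix and matrix modification (0.0019 and 0.428), BMP and TGF-beta response (0.00512 and 0.288) and interferon response (0.00512 and 0.873), so none passed with an estimated correlation.

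The proliferation difference has 3 explanations that were weighed. Correlation between the genes of the list could produce it, since the adjusted p is 0.288 with an estimated correlation, which fits this explanation. Grouping of the clones by chance may also do so: 2 of 10 splits of the 6 clones gave a difference as large as the real one of -0.94, the highest other being 1.01, and 10 splits are too few for a share under 0.05. An effect of the deletion on cell division under hypoxia stays an open hypothesis, for which KO3, with a mean response of 0.52 inside the WT range of 0.40 to 1.25, would have to be an exception.

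The matrix, BMP and interferon differences were not weighed further, and 3, 2 and 3 of 10 splits of the clones gave a difference of mean responses as large. Interferon genes were high in both WT6 libraries. Leaving out only the hypoxic one left the normoxic one without its pair, and the difference then had the other direction (adjusted p = 0.0886). With both kept, the mean response was 0.31 in WT6, against 0.08 in WT4 and 0.11 in WT5. It was 0.19 in KO3, -0.7 in KO4 and -1.55 in KO5, so KO3 lay within the WT range.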

How the results depend on the processing

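Counts of genes and of lists past the threshold depended on the setting in each comparison. Of 70 genes named as changed in WT, 48 passed under every setting chosen in advance, and of 54 in KO, 34 did. None of these changed sign. Of the named genes not past the threshold, 13 of 15 in KO against WT in normoxia, 5 of 8 in hypoxia and 0 of 6 in the interaction passed under some such setting, and TUBA4A, the 1 called gene of the former, was lost under some. For KO against WT these settings include the number used as a block, described below. Leaving out both libraries of a clone, and the block with an estimated correlation for lists, were chosen after seeing the data. The cause of each change was not tested.

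The count in WT (4036) was 6184 with limma-voom and a correlation within clone and 5991 with clone as a block. It was 2541 to 3563 with 1 library left out. The count in KO (2586) was 4923 with that correlation, 4684 with clone as a block and 1130 to 2435 with 1 library left out. It was 1656, 706 and 830 without clones KO3, KO4 and KO5. EPAS1 in KO had log2 fold changes of -0.84, -1.18 and -1.11 without these clones, not past the threshold.

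For KO against WT in normoxia the count of 1 became 154 with DESeq2 and 3 without the low-count filter. With the number used as a block, which pairs nothing between genotypes, it became 1522 (972 higher and 550 lower). KO3 and WT6 share their number with no clone of the other genotype, so that block takes up their levels. Its KO to WT difference in either oxygen condition rests mainly on KO4 and KO5 against WT4 and WT5. The normoxic count was 0 with limma-voom, with limma-voom and a correlation within clone, with a length offset and with only the groups compared. With 1 library left out it was 0 to 406, without clone KO3 769, and without KO4, KO5 or WT6 0. The EPAS1 log2 fold change ran from -0.27 to 0.06 with 1 library left out and was 0.02 without clone KO5. The interferon list had adjusted p from 2.12e-06 to 0.293 with 1 library left out, and it turned higher without normoxic WT6 (0.0295), without clone WT6 (2.17e-05) and with the number block (0.00265). In hypoxia the count of 0 became 77 with DESeq2, 1 without the filter, 1 with a length offset, 983 with the number block (686 higher and 297 lower), 0 to 7 with 1 library left out and 228 without clone KO3. The interaction count of 0 became 2 with DESeq2, 0 to 1 with 1 library left out and 2 without clone KO3.

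With an estimated correlation the lists past the threshold went from 6 to 2 in WT, from 7 to 2 in KO, and from 6, 7 and 4 to 0 in the other comparisons. With fry they were 10 in WT and 0 in each of the latter 3. The block with an estimated correlation gave 3 in WT, 2 in KO and 0 in the interaction. The interaction lists numbered 2 to 6 with 1 library left out and 2 without clone WT6. The interferon interaction had adjusted p from 8.92e-15 to 0.4 with 1 library left out, in the other direction without hypoxic WT6 (0.0886). With clone as a block, cholesterol genes (0.0437) and endothelial identity genes (0.0465) also passed in WT, interferon genes (0.0229) in KO and core HIF targets (0.0463) in the interaction, and no other list call changed in these comparisons.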

Other observations

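The mean response of the core HIF list was 1.66 in WT4, 1.81 in WT5, 1.62 in WT6, 1.78 in KO3, 1.81 in KO4 and 1.88 in KO5, and that of glycolysis 1.38, 1.54, 1.32, 1.45, 1.36 and 1.55 in the same order. Single members departed from these means: LOX went from 12.2 ± 4.27 to 139 ± 51.4 CPM in WT and from 355 ± 302 to 343 ± 145 CPM in KO, having been 20.3 CPM in normoxic KO3, 439 in KO4 and 607 in KO5.

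Apart from the chromosome 11 difference between oxygen conditions, the tests in this part were chosen only after the results were seen. KO4 lay between KO5 and the WT clones. If it held 2 cell populations, the share on KO5-high genes and the share kept on KO5-low genes would sum to 1. The sums were 0.99 in normoxia and 0.97 in hypoxia. The hypoxic kept share of 0.527 had quartiles of 0.419 to 0.886. Among the WT clones and KO3 the sums ran from 0.84 (WT5) to 1.09 (WT6) in normoxia. In hypoxia they ran from 0.61 (WT5) to 1.23 (WT6). The baseline of the shares was the mean of the WT clones, so a clone that resembles them has a sum near 1 by construction. These sums therefore show the spread between clones and cannot tell whether a sum near 1 is particular to a mixture. In a mixture, the part of the KO5 chromosome 11 shift seen in KO4 should be smaller in hypoxia than in normoxia. The share on KO5-high genes was smaller in hypoxia, and the part differed by 0.47 (0.39 to 0.54), normoxia minus hypoxia. Intervals for this part came from 2000 resamplings of the chromosome 11 genes, so they do not cover the spread between libraries or clones. The size of that part depended on the baseline, as against the median of the 6 libraries it was 0.73 in normoxia and 0.26 (0.21 to 0.32) in hypoxia, below the hypoxic share of 0.444, whereas from the WT clones it was 0.79 and 0.36 (0.32 to 0.42), overlapping the quartiles of the share (0.358 to 0.488) but not its median. One intermediate state on a log scale predicts a kept share of 0.008 where 0.24 was seen, and an effect shared by all KO clones is hard to square with the KO3 share of 0.0. A mixture stays open as a hypothesis, as does a linear intermediate state in every cell, which could give the same sums.

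Shifts of whole chromosomes in KO5 and WT6 have 2 explanations. GC content and transcript length could move many genes together, but regression on them left at least 76.5% of each shift. Different copy number between clones was not decided. The 6 of 6 chromosomes with the same sign in both libraries of the clone had been picked by these medians (a shift of at least 0.2 in either library), and DNA was not analysed here.

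Regrouping the libraries of a comparison gives 10 splits, too few for a share under 0.05. The real split had 4036 genes in WT hypoxia and 2586 in KO hypoxia, where the highest other had 1 and 0, so 1 of 10 splits reached the real count in each. For KO against WT in normoxia 1 of 10 splits did (1 gene, highest other 0). In hypoxia and for the interaction the real count was 0, which 10 of 10 splits reach whatever the data, so nothing was tested there (highest other 0 in each).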
